A study of Mus musculus with 18 samples.

How the data were processed

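Poly(A) RNA of mouse embryonic fibroblasts was extracted with TRIzol, made into libraries with an NEBNext Ultra RNA kit and sequenced as paired reads on a NovaSeq 6000, per the labels. The authors deposited a table of FPKM (fragments per kilobase of gene model, scaled to the mapped fragments of the library), with a column for each of 18 libraries. Their processing notes name the build mm10 and state neither the aligner, the quantifier, the annotation release nor how reads shared between copies of a gene were counted, so values of gene families with near-identical copies (Oas, Ifit, histone and ribosomal protein genes) are uncertain. Whole read counts could not be recovered from the values, so the depth of each library is unknown and no counting interval is given. Strand was not stated. Library totals ran from 325800 to 428434 FPKM, and no pair of libraries held identical values.

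Of 32291 identifiers in the table, 32235 were named from GENCODE M21 (mm10), which also gave coordinates, exon length and GC content, and 56 were unnamed, 6 of them rows of the vector. Junb was read with caution because its values at time point 2 moved between 0 and above 20 within groups. Genes with FPKM of at least 1 in at least 3 libraries were tested, 12478 in all, of which 11917 were protein-coding. Values were taken as log2(FPKM + 1), with a pseudocount of 1. A mean per group was fitted with limma 3.58.1 in R 4.3.3, the variance being moderated with a trend (eBayes), and two-sided tests were adjusted by Benjamini-Hochberg within each of 11 comparisons and called at an adjusted p under 0.05. The comparisons were SV40T against vehicle, vehicle against control and SV40T against control at each time point, time point 2 against 1 in each treatment, and the difference between time points of SV40T against vehicle and of vehicle against control. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No count-based test was used, since the values are not counts.

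The groups, comparisons, gene lists, rule for named genes and most alternatives were chosen before the data were examined. The rule named, in each comparison, the 6 largest increases and decreases among called genes with non-overlapping groups and a mean of at least 5 FPKM in the higher group, leaving out predicted genes, up to 3 called members of each list with the smallest adjusted p, and Trp53, Rb1, Cdkn1a, Cdkn2a, Mdm2 and Mki67. For SV40T against control and for the differences between time points it named the last 6 genes and the 4 largest in each direction. The text prints examples of these. The 24 lists covered DNA replication, mitosis, chromosome structure and chromatin, homologous recombination and damage checkpoint, p53 targets, CDK inhibitors, collagens and structural matrix, matrix proteases and inhibitors, contractile genes, secreted factors of senescence, type I interferon response, glycolysis, cholesterol synthesis, the unfolded protein and integrated stress response, lysosome, mitochondrially encoded genes, fibroblast identity, and markers of macrophages, endothelium, epithelium, skeletal muscle, neural and glial cells, adipocytes and erythroid cells. Each list was tested with camera of limma with the preset correlation 0.01 and again with a correlation estimated from the data. Of 253 list tests, 134 were called with the preset correlation and 23 of these also with the estimated one. None of the 7 erythroid genes reached the filter, so that list was not tested. Mx1 and Mx2 of the interferon list were not in the table.

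The test was checked on simulated data, drawn from normal distributions with the mean and residual SD of each gene, with known changes added to the SV40T libraries of time point 2. Of 67 genes changed by 0.5 on the log2 scale 44.78% were called, and of 67 changed by 1 the share was 91.04%. All 66 genes changed by 2 were called, as were 12 of 12278 unchanged genes. The simulated genes varied independently and with the same spread in every library. The real libraries had length and GC trends across genes, so these shares need not hold for them. The alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at FPKM 5, median-ratio scaling, quantile normalization, a further requirement of a 2-fold change, a fit of only the groups compared, array weights, the replicate number as a block, and leaving out each library in turn. Replicate numbers showed no clear pairing of the libraries, though a weak one is not ruled out. Within time point 1 the residual correlations of equal numbers across treatments ran from -0.094 to 0.196, and within time point 2 from -0.263 to 0.158. Between time points within a treatment they ran from -0.171 to 0.165. Alternatives added after seeing the data removed the trend of each library on exon length, GC content or both with lowess (span 0.3), left out vehicle replicate 1 of time point 1, or left out the vector rows. A second list of 22 macrophage genes and a list of 12 mesothelial genes were also drawn up at that stage, before the values of those genes were looked at, and 17 and 10 of them were tested.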

Results

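Messenger RNA was measured by poly(A) RNA sequencing in mouse embryonic fibroblasts (MEFs), primary cells grown out of embryos that divide a limited number of times in culture. The 18 libraries fell into 6 groups of 3 libraries each, from 3 treatments at 2 time points. Cells were left uninfected (control), infected with an empty lentivirus (vehicle), or infected with a lentivirus carrying SV40T, the large T antigen of simian virus 40, which binds p53 and the retinoblastoma proteins. Time point 1 was the primary stage, and time point 2 was reached when control or vehicle cultures no longer proliferated. The deposited values are FPKM, so the number of reads behind each value is unknown and a gene listed at 0 cannot be given a lower limit of detection. The libraries summed to between 325800 and 428434 FPKM, with 11032 to 11723 genes at FPKM 1 or above, and 12478 genes were tested. Values are mean FPKM ± SD (n = 3). Folds are from log2(FPKM + 1), relative to the median change of all tested genes. The adjusted p-values of single genes, and the counts of genes that rose or fell, test the change before that median was subtracted. Where the median was positive, the printed increases are smaller and the printed decreases larger than the change tested. Except in fits of only the groups compared, the p-values measure the spread within groups pooled over all 18 libraries, not that of the groups compared alone. Vehicle libraries of time point 1 varied most, with replicate correlations down to 0.9545, against 0.9892 in the next group, control at time point 2. The spread can be technical, since nothing states that the 3 libraries of a group came from separate cultures or embryos.

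The first principal component held 49.8% of the variance and separated SV40T cells from the others, most widely at time point 2, and the second held 23.6% and separated the time points. Vehicle replicate 1 at time point 1 stood apart. Its total of 428434 FPKM exceeded that of the other 17 libraries, and 19.78% of it came from ribosomal protein genes, against 10% to 13.19% elsewhere. Its values fell with gene length (Spearman rho across genes -0.634, genes not being independent replicates). The other vehicle and control libraries of time point 1 also differed in their trend with GC content (rho 0.499 and 0.376 in vehicle, -0.190 to -0.347 in control).

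**Figure D1:**
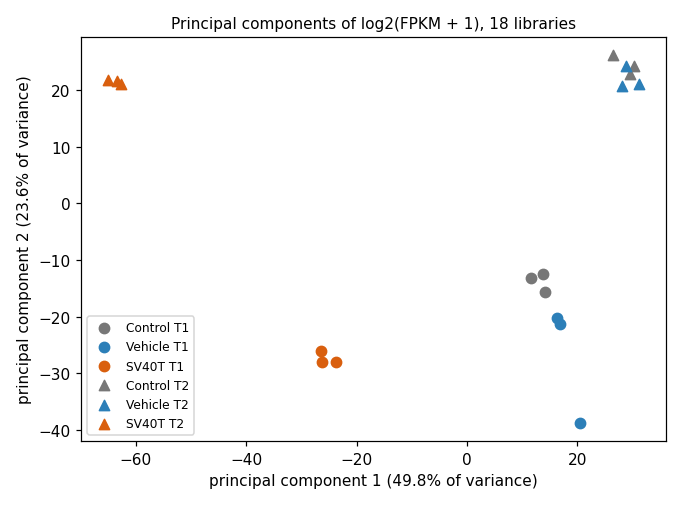
Scores of the 18 libraries on the first and second principal components of log2(FPKM + 1), a point per library, coloured by treatment and with the time points marked apart. The SV40T libraries of time point 2 lie at the far end of the first component, and the control and vehicle libraries of time point 2 lie together.

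**Figure D2:**
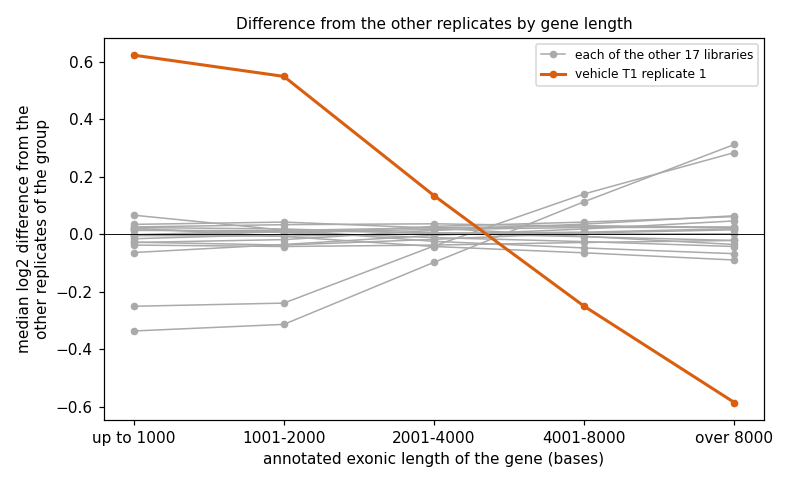
Median log2 difference of each library from the other replicates of its group, by class of annotated exonic length in bases, a line per library. Vehicle replicate 1 at time point 1 runs from 0.623 in the shortest class to -0.586 in the longest, and the lines that run the opposite way are the other vehicle libraries of time point 1, which are compared with it.

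The rows of the vector gave the check of the treatment. The SV40T transcript averaged 195 ± 13.5 FPKM in SV40T cells at time point 1 and 338 ± 8.48 at time point 2. It was listed at 0 in all control libraries, and stood at 0.194 ± 0.0585 and 0.0731 ± 0.00871 in vehicle cells. The puromycin resistance row, a selection marker carried by both viruses, averaged 1005 ± 22.5 FPKM in vehicle and 258 ± 3.95 in SV40T cells at time point 1, and 473 ± 21.2 and 227 ± 12.1 at time point 2. With limma, SV40T was higher than in vehicle cells by 7.36 on the log2 scale at time point 1 (adjusted p = 3.65e-20) and 8.30 at time point 2 (adjusted p = 5.29e-21). The puromycin row changed by -1.96 (adjusted p = 2.49e-12) and -1.05 (adjusted p = 2.28e-10) in the same tests. The cmvPromoter row did not pass at time point 1 (adjusted p = 0.698) and was higher in SV40T cells at time point 2 (1.22, adjusted p = 0.000293). The infections were thus not matched in vector RNA.

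**Figure D3:**
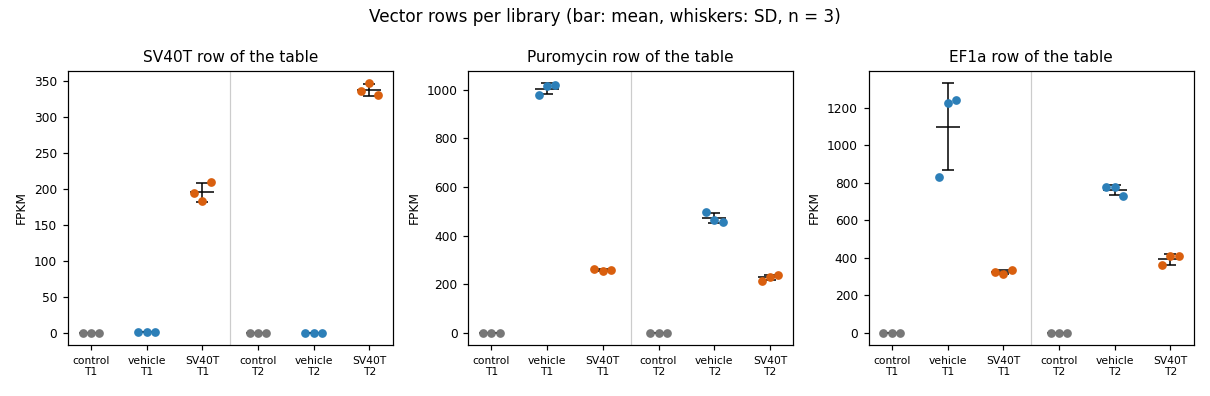
FPKM of the SV40T, puromycin and EF1a rows of the vector in the 6 groups (T1 and T2 are the time points), a point per library with a bar at the mean and whiskers for the SD (n = 3). The SV40T row averages 195 and 338 FPKM in SV40T cells, the puromycin row is highest in vehicle cells at time point 1, and control libraries are listed at 0.

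The comparison of SV40T with vehicle cells at time point 1 asks what large T antigen changed beyond infection with the empty virus, early after infection. It cannot separate large T antigen from the difference in vector RNA between these cells. Genes of the type I interferon response rose together, 33 of 33 tested (33 adjusted over the list alone). Isg15, a ubiquitin-like protein attached to others during antiviral defence (ENSMUSG00000035692, mm10 chromosome 4, 156199424 to 156200818), averaged 251 ± 21.9 FPKM in SV40T and 17.2 ± 11.9 in vehicle cells, 14.5-fold higher (adjusted p = 1.08e-07). Usp18, the protease that removes Isg15, stood at 58.1 ± 5.33 against 2.81 ± 1.18 (14.8-fold, adjusted p = 9.18e-10). The chemokine Cxcl10 stood at 21.4 ± 2.3 against 1.05 ± 0.849 (10.7-fold, adjusted p = 2.22e-07). Proliferation genes rose as well. DNA replication genes rose in 43 of 46 (43 adjusted over the list alone), and mitosis genes in 39 of 41 (39). The same held for genes of chromosome structure and chromatin in 28 of 29 (29), and genes of homologous recombination and the damage checkpoint in 35 of 36 (35). Part of the mitosis, chromatin and homologous recombination differences lay in the vehicle reference, which was below control cells on these lists. The summed FPKM of the mitosis list averaged 1010 ± 37.3 in SV40T, 513 ± 22.3 in vehicle and 769 ± 45 in control cells. For chromatin the sums were 856 ± 7.8, 442 ± 22.2 and 551 ± 25.5, and for homologous recombination 304 ± 13, 149 ± 16.7 and 197 ± 10.9. Ccna2, which encodes cyclin A2 of S phase and mitosis, averaged 31.3 ± 0.16 against 12.9 ± 0.841 FPKM (2.15-fold, adjusted p = 3.38e-09). Lig1, the ligase that joins Okazaki fragments, averaged 27 ± 0.835 against 9.77 ± 0.381 (2.41-fold, adjusted p = 1.94e-09).

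Thy1, a surface glycoprotein of fibroblasts (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), averaged 129 ± 9.13 FPKM in SV40T cells against 504 ± 52.9 in vehicle cells at time point 1, 4.19-fold lower (adjusted p = 1.9e-10). Sod3, the extracellular superoxide dismutase, averaged 2.75 ± 0.505 against 16.6 ± 1.62 (5.09-fold lower, adjusted p = 8.75e-10). The chemokine Cxcl14 averaged 3.17 ± 0.305 against 25.5 ± 4.02 (6.8-fold lower, adjusted p = 1.94e-06). Collagens and structural matrix genes fell in 27 and rose in 4 of 48 (27 and 4 adjusted over the list alone). Matrix proteases and inhibitors fell in 15 and rose in 1 of 24 (15 and 2), and secreted factors of senescence fell in 13 of 18 (13). Among the last, Fgf7, a growth factor for epithelia, averaged 6.5 ± 0.384 against 20.9 ± 0.98 (3.15-fold lower, adjusted p = 1.15e-06). Cholesterol synthesis genes fell in 19 of 20 (19), with Hmgcs1, which makes the HMG-CoA of that pathway, at 26.5 ± 0.237 against 64.1 ± 2.4 (2.56-fold lower, adjusted p = 6.75e-09).

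Trp53, which encodes p53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873), averaged 92.1 ± 1.99 FPKM in SV40T and 48.2 ± 1.41 in vehicle cells (1.76-fold, adjusted p = 1.75e-08). Rb1, which encodes the retinoblastoma protein, averaged 5.48 ± 0.284 against 2.44 ± 0.829 (1.78-fold, adjusted p = 3.35e-05). Mdm2, the ligase that degrades p53 and is a p53 target, averaged 96.2 ± 9.01 against 62.2 ± 9.6 (1.43-fold, adjusted p = 0.00149). Of 26 p53 targets, 11 rose and 2 fell (12 and 2 adjusted over the list alone), and the list test did not pass (adjusted p = 0.427). Cdkn2a, whose row cannot separate the inhibitor p16Ink4a from p19Arf, averaged 54.6 ± 1.11 against 39.2 ± 20 (adjusted p = 0.0322, lost in 9 alternatives, among them leaving out any SV40T library or vehicle replicate 2 or 3). Cdkn1a, the p53-induced inhibitor p21, averaged 252 ± 15.1 against 211 ± 6 (adjusted p = 0.017, lost after median-ratio scaling, without SV40T replicate 1 and in other alternatives).

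With limma, 5925 of 12478 genes were called at time point 1, 3830 higher and 2095 lower in SV40T cells, and 637 of them changed at least 2-fold. The groups did not overlap in 6569 genes (52.64%, against 10% by chance). The median change of all genes was 0.110, and the share of called genes that were higher, 64.64%, was 47.5% after median-ratio scaling and 49.8% after quantile normalization. In the camera test with a preset correlation of 0.01, median changes relative to all genes were 2.31 for the interferon list (adjusted p = 6.46e-27) and 1.07 for DNA replication (adjusted p = 2.34e-21). They were 0.96 for mitosis (adjusted p = 1.99e-17), 1.05 for chromatin (adjusted p = 7.94e-15) and -0.98 for cholesterol synthesis (adjusted p = 2.7e-13). With an estimated correlation these lists stayed called (adjusted p = 0.0147, 0.0316, 0.0408, 0.0316 and 0.0316). So did matrix proteases (-0.81, adjusted p = 7.41e-08 and 0.0245), senescence factors (-1.09, adjusted p = 1.06e-06 and 0.00324) and fibroblast identity (8 of 12 lower, 8 adjusted over the list alone, -0.84, adjusted p = 1.49e-05 and 0.0054). Among the calls lost with an estimated correlation were those of homologous recombination (0.86, adjusted p = 3.57e-14, and adjusted p = 0.0674 with an estimated correlation) and collagens (-0.57, adjusted p = 6.74e-09, and adjusted p = 0.191 with an estimated correlation). Contractile genes fell in 7 and rose in 2 of 17 (7 and 2), with a camera adjusted p = 0.0283 (adjusted p = 0.478 with an estimated correlation), and their median before that adjustment was -0.33 but 0.01 after quantile normalization. Fitting only these groups called 2867 genes, and 6545 were called without vehicle replicate 1.

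At time point 2 the same contrast asks how SV40T cells differed at the end of the cultures, when control or vehicle cells no longer proliferated. The interferon list again rose in 33 of 33 genes (33 adjusted over the list alone), with Isg15 at 519 ± 39.3 FPKM against 10.9 ± 3.1 in vehicle cells (37.8-fold, adjusted p = 3.77e-10). Cxcl10 stood at 76 ± 7.42 against 0.369 ± 0.342 (48.4-fold, adjusted p = 9.8e-11). Among proliferation genes, DNA replication rose in 45 of 46 (45), mitosis in 41 of 41 (41), chromatin in 29 of 29 (29) and homologous recombination in 36 of 36 (36). Ccna2 averaged 57.5 ± 2.46 against 12.2 ± 0.492 (3.74-fold, adjusted p = 6.17e-13). Lmnb1, a lamin lost in senescent cells, averaged 69.9 ± 0.75 against 9.4 ± 1.04 (5.77-fold, adjusted p = 1.65e-12), and Mki67, a marker of cycling cells, 31 ± 1.42 against 8.75 ± 0.889 (2.78-fold, adjusted p = 1.17e-08). Trp53 averaged 88.6 ± 5.97 against 38.6 ± 1.04 (1.91-fold, adjusted p = 1.23e-10) and Cdkn2a 404 ± 35.9 against 174 ± 10.3 (1.95-fold, adjusted p = 9.32e-05). Mdm2 stood at 86.7 ± 11.9 against 72.3 ± 5.14 (adjusted p = 0.117, called higher without SV40T replicate 2 and without vehicle replicate 1 of time point 1). Cdkn1a stood at 203 ± 20.8 against 211 ± 8.34 (adjusted p = 0.531), though Cdkn1a was called lower after median-ratio scaling.

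Matrix, contractile and secreted genes were lower in SV40T cells at time point 2. Collagens and structural matrix fell in 39 and rose in 4 of 48 (40 and 4 adjusted over the list alone). Matrix proteases fell in 20 and rose in 1 of 24 (20 and 1), contractile genes fell in 12 of 17 (12), and senescence factors fell in 14 and rose in 1 of 18 (14 and 1). Mfap5, a microfibril protein, averaged 1.95 ± 0.099 FPKM against 45.6 ± 1.7 (18.7-fold lower, adjusted p = 3.53e-12). Ccn2, a matricellular growth factor, averaged 111 ± 13.7 against 537 ± 51.9 (5.71-fold lower), and Myh11, the myosin of smooth muscle, 0.865 ± 0.268 against 15.6 ± 0.838 (10.6-fold lower). Thy1 stood at 178 ± 11.3 against 617 ± 14.5 (4.09-fold lower, adjusted p = 5.08e-11).

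Markers of other cells moved with these groups at time point 2. Macrophage genes fell in 14 of 15 (14 adjusted over the list alone), and their summed FPKM was 9.69 ± 0.954 in SV40T, 254 ± 94.3 in vehicle and 361 ± 73.5 in control cells, where at time point 1 it was 116 ± 4.33, 95.8 ± 30.5 and 128 ± 16.5. Lyz2, the lysozyme of macrophages (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), averaged 1.71 ± 0.0964 against 155 ± 60.3 in vehicle cells (64.9-fold lower, adjusted p = 3.27e-12). C1qc, a complement subunit made by macrophages, averaged 0.24 ± 0.0456 against 12.9 ± 5.23. Of 12 epithelial genes only 5, all keratins, passed the filter on low values, which a gene could pass by its rise in this group alone, and all 5 rose (5 adjusted over the list alone). The other 7, among them Epcam and Cdh1, averaged at most 0.254 FPKM in SV40T cells. Krt7, a keratin of simple epithelia, averaged 29.2 ± 5.43 against 1.29 ± 0.264 (11.1-fold). Krt14, a keratin of stratified epithelia, stood at 39.4 ± 10.4 and was listed at 0 in vehicle cells. Msln, a surface protein of mesothelium (ENSMUSG00000063011, chromosome 17, 25748613 to 25754378), averaged 88.8 ± 9.04 against 0.853 ± 0.311 (41.2-fold, adjusted p = 9.69e-16). Adipocyte genes fell in 4 and rose in 1 of 5 (4 and 1).

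At time point 2, limma called 8218 genes, 5699 higher and 2519 lower in SV40T cells, of which 2102 changed at least 2-fold. The groups did not overlap in 9912 genes (79.44%, against 10% by chance). The median change was 0.243, and 69.35% of called genes were higher, against 49.3% after median-ratio scaling and 50.6% after quantile normalization. Median changes relative to all genes were 3.27 for interferon (camera adjusted p = 7.22e-17), and 1.91 for DNA replication (adjusted p = 4.83e-18). They were 1.57 for mitosis (adjusted p = 2.32e-15), 1.63 for chromatin and 1.23 for homologous recombination (adjusted p = 1.08e-11 for both). With an estimated correlation none of these stayed called (adjusted p = 0.0617, 0.0617, 0.0655, 0.0655 and 0.0805). Matrix proteases (-1.23, adjusted p = 2.37e-10) and senescence factors (-1.46, adjusted p = 1.65e-07) stayed called, with adjusted p = 0.0168 and adjusted p = 0.00186 with an estimated correlation. Collagens (-1.27, adjusted p = 2.27e-13), contractile genes (-1.19, adjusted p = 1.65e-07), macrophage genes (-2.51, adjusted p = 1.34e-11), the 5 keratins of the epithelial list (2.96, adjusted p = 0.000535) and adipocyte genes (-1.14, adjusted p = 0.00393) did not, with adjusted p = 0.0805, 0.0789, 0.0789, 0.0702 and 0.0617 with an estimated correlation. The adipocyte call also ended after quantile normalization.

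**Figure D4:**
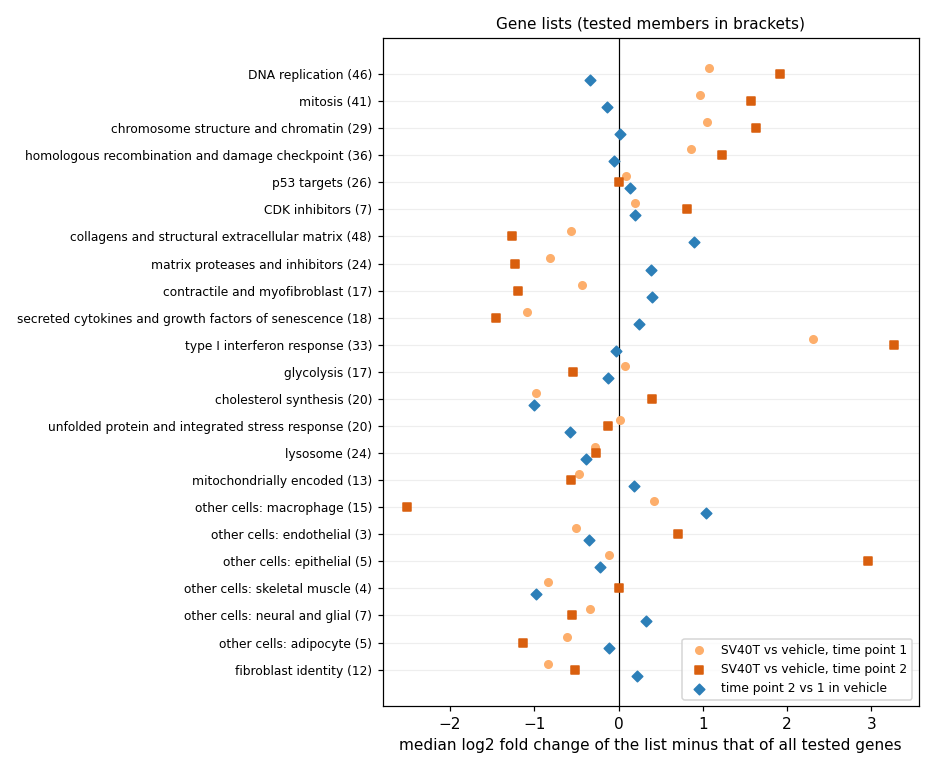
Median log2 fold change of the tested members of each gene list minus that of all tested genes, for SV40T against vehicle at both time points and for time point 2 against 1 in vehicle cells, a point per list and comparison. Interferon and proliferation lists lie to the right and collagen and protease lists to the left for SV40T at both time points, and the contractile list at time point 1 has a median of 0.01 after quantile normalization.

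**Figure D5:**
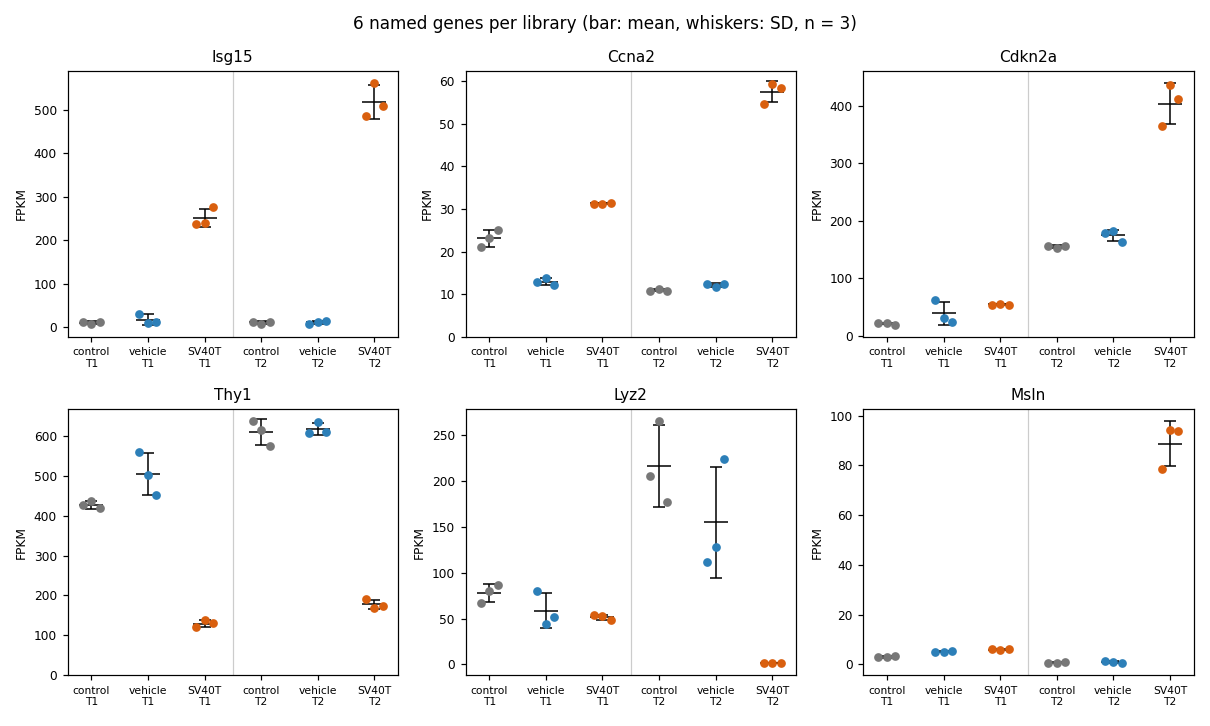
FPKM of Isg15, Ccna2, Cdkn2a, Thy1, Lyz2 and Msln in the 6 groups (T1 and T2 are the time points), a point per library with a bar at the mean and whiskers for the SD (n = 3). Isg15 in SV40T cells averages 251 at time point 1 and 519 at time point 2, and Lyz2 in SV40T cells stands at 1.71 at time point 2.

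SV40T against uninfected control cells asks what infection and large T antigen changed together, since the reference carried no virus. At time point 1 the interferon list rose in 32 of 33 genes (32 adjusted over the list alone, median 2.01 relative to all genes, camera adjusted p = 1.42e-27, and adjusted p = 0.0101 with an estimated correlation) and DNA replication in 41 of 46 (43, median 0.94, adjusted p = 2.18e-20, and adjusted p = 0.032 with an estimated correlation). Mitosis rose in 23 and fell in 1 of 41 (23 and 1, median 0.31, adjusted p = 4.06e-06, and adjusted p = 0.218 with an estimated correlation), and Mki67 did not pass (adjusted p = 0.156, called higher without vehicle replicate 1). All 13 mitochondrially encoded genes fell (13, median -1.31, adjusted p = 5.01e-11, and adjusted p = 0.00347 with an estimated correlation). Vehicle cells were also below control on that list. Its summed FPKM at time point 1 averaged 25860 ± 925 in control, 14325 ± 257 in vehicle and 10903 ± 346 in SV40T cells. Cdkn2a averaged 54.6 ± 1.11 against 21.1 ± 1.48 (2.45-fold, adjusted p = 9.37e-05), and Spp1, a secreted matrix phosphoprotein, 77 ± 8.1 against 408 ± 20.3 (5.42-fold lower). At time point 2, Lyz2 stood at 1.71 ± 0.0964 against 216 ± 44.9 (91.4-fold lower) and Cdkn2a at 404 ± 35.9 against 155 ± 2.35 (2.24-fold, adjusted p = 2.59e-05). All 46 DNA replication genes (46, median 1.91, adjusted p = 3.14e-19) and all 33 interferon genes (33, median 3.24, adjusted p = 1.27e-17) rose there, each with adjusted p = 0.0468 with an estimated correlation. With limma, 5345 genes were called at time point 1 (3059 higher, 2286 lower, 8354 with array weights) and 7961 at time point 2 (5422 higher, 2539 lower). At time point 1, 57.23% of called genes were higher, against 50.2% after median-ratio scaling and 48.9% after quantile normalization. The median change at time point 2 was 0.212, and 68.11% of called genes were higher, against 49.4% and 50.1% after median-ratio scaling and quantile normalization.

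Vehicle against control asks what the empty virus changed. At time point 1 mitosis genes were lower in vehicle cells, in 35 of 41 (36 adjusted over the list alone), as were chromatin genes in 23 of 29 (23), homologous recombination genes in 22 of 36 (30) and mitochondrially encoded genes in 12 of 13 (12). Ccna2 averaged 12.9 ± 0.841 FPKM against 23.1 ± 1.95 in control cells (1.63-fold lower, adjusted p = 5.13e-06), and Mki67 7.99 ± 2.2 against 16.7 ± 1.37 (1.9-fold lower, adjusted p = 0.00016). The respiratory complex I subunit mt-Nd2 averaged 744 ± 65.3 against 1412 ± 55.8 (1.8-fold lower, adjusted p = 1.5e-05). Sox10, the transcription factor of neural crest and glia, averaged 1.23 ± 0.199 against 4.6 ± 0.382 (2.37-fold lower, adjusted p = 8.74e-08). Ngfr, a neurotrophin receptor of Schwann cells, averaged 3.96 ± 1 against 14 ± 0.811 (2.89-fold lower, adjusted p = 1.58e-06). Neural and glial genes fell in 4 of 7 (4). Trp53 stood at 48.2 ± 1.41 against 49.7 ± 1.43 (adjusted p = 0.605).

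At time point 1 limma called 4132 genes between vehicle and control, 1577 higher and 2555 lower in vehicle cells, of which 99 changed at least 2-fold. The share of called genes that were higher was 38.17%, against 54.2% after median-ratio scaling and 47.4% after quantile normalization. The groups did not overlap in 5406 genes (43.32%, against 10% by chance). Camera adjusted p-values were 3.38e-14 for mitosis, 1.09e-08 for chromatin, 2.61e-07 for homologous recombination, 2.77e-08 for mitochondrially encoded and 0.00823 for neural and glial genes. With an estimated correlation the mitochondrially encoded list stayed called (adjusted p = 0.0234), and the others did not (adjusted p = 0.172, 0.21, 0.494 and 0.143), and the neural and glial call also ended without vehicle replicate 3. The count was 2474 after the length and GC trends of the libraries were removed, 1812 after the GC trend alone was, 2490 without control replicate 2 and 2606 without control replicate 3. It was 30 when only these groups were fitted, and 4429 when vehicle replicate 1, which widened the spread in that fit, was also left out.

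At time point 2 limma called 8 genes between vehicle and control, 5 of them vector rows, and 591 genes had an unadjusted p under 0.05. The 3 mouse genes were lower in vehicle cells. Ngfr averaged 0.799 ± 0.166 FPKM against 2.48 ± 0.351 (adjusted p = 0.00423), and Cadm4, an adhesion protein of myelinating glia, 1.5 ± 0.114 against 3.66 ± 1.05 (adjusted p = 0.00433). Sox10 averaged 0.251 ± 0.0227 against 0.827 ± 0.0206 (adjusted p = 0.0135, lost in 12 alternatives, among them leaving out any control replicate or vehicle replicate 1 or 2). Macrophage genes were called in 0 of 15 over all genes and were lower in 11 of 15 adjusted over the list alone (median -0.48 relative to all genes, camera adjusted p = 3.5e-14, and adjusted p = 0.456 with an estimated correlation). These genes are not independent, and the groups overlapped in their summed FPKM. The sums were 189.5, 209.5 and 361.8 in vehicle and 348.1, 440.7 and 295.5 in control libraries. The groups did not overlap in 1586 genes (12.71%, against 10% by chance). Array weights called 28 genes, and without the filter on low values 25 were called. Leaving out vehicle replicate 3 of time point 2 gave 24, and leaving out vehicle replicate 1 of time point 1 gave 14.

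Time point 2 against 1 asks what changed as cultures aged. In control cells Igfbp2, which binds insulin-like growth factors, rose from 11.1 ± 0.578 to 480 ± 64.4 FPKM (39.1-fold, adjusted p = 9.58e-10). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) rose from 21.1 ± 1.48 to 155 ± 2.35 (6.97-fold, adjusted p = 6.65e-08). Cdkn2b, the neighbouring inhibitor p15Ink4b, rose from 19.3 ± 0.656 to 31.9 ± 1.53 (1.6-fold, adjusted p = 0.000483). Ccna2 fell from 23.1 ± 1.95 to 10.9 ± 0.26 (2.04-fold, adjusted p = 3.58e-08). Mitosis genes fell in 38 of 41 (40 adjusted over the list alone), DNA replication in 38 of 46 (40) and cholesterol synthesis in 19 of 20 (19). Collagens rose in 31 and fell in 1 of 48 (34 and 3), and macrophage genes rose in 12 of 15 (12). In vehicle cells Igfbp2 rose from 25.9 ± 10.9 to 558 ± 157 (20.5-fold, adjusted p = 2.38e-09). There Cdkn2a rose from 39.2 ± 20 to 174 ± 10.3 (4.53-fold, adjusted p = 6.69e-07) and Ogn, a matrix proteoglycan, from 2.86 ± 0.502 to 29 ± 4.77 (7.46-fold). Collagens rose in 35 of 48 (35), macrophage genes in 12 of 15 (12), and DNA replication fell in 23 of 46 (24) and mitosis in 11 of 41 (11).

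In SV40T cells Cdkn2a also rose, from 54.6 ± 1.11 to 404 ± 35.9 FPKM (6.27-fold, adjusted p = 1.61e-08), and so did proliferation genes. DNA replication rose in 39 of 46 (39 adjusted over the list alone), mitosis in 34 of 41 (34) and interferon genes in 28 of 33 (28), with Mki67 rising from 20 ± 0.741 to 31 ± 1.42 (1.32-fold, adjusted p = 0.00116). Upk3b, a uroplakin also made by mesothelium, rose from 0.644 ± 0.107 to 38.9 ± 5.16 (20.9-fold, adjusted p = 1.35e-14). Lyz2 fell from 51.6 ± 2.82 to 1.71 ± 0.0964 (22.5-fold, adjusted p = 3.67e-10). Macrophage genes fell in 14 of 15 (14) and 4 of the 5 tested epithelial genes, the keratins, rose (4). Col3a1, a fibrillar collagen, rose from 78.7 ± 11.7 to 582 ± 49.2 (6.34-fold), although collagens as a list rose in 21 and fell in 7 of 48 with a median of 0.0 relative to all genes.

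Limma called 4501 genes over time in control cells (2410 higher, 2091 lower), 5219 in vehicle cells (3121 and 2098) and 7081 in SV40T cells (5207 and 1874). For control cells 53.54% of called genes were higher, against 50.5% after median-ratio scaling and 45.5% after quantile normalization. In vehicle cells 59.8% of called genes were higher, against 49.6% after median-ratio scaling and 47.3% after quantile normalization, and in SV40T cells 73.53% against 52% and 51.8%, where the median change was 0.213. The control count was 7327 with array weights and 6759 without vehicle replicate 1 of time point 1, and the vehicle count was 1939 when only those groups were fitted. In control cells camera gave adjusted p = 1.07e-19 for mitosis, 5.2e-14 for DNA replication, 2.03e-12 for cholesterol synthesis, 1.55e-11 for collagens and 3.99e-08 for macrophage genes. None stayed called (adjusted p = 0.0768, 0.107, 0.0768, 0.171 and 0.187 with an estimated correlation). The lists named for vehicle cells had adjusted p = 1.76e-10 for collagens, 1.15e-05 for macrophage, 5.8e-08 for DNA replication and 0.0225 for mitosis (adjusted p = 0.3, 0.356, 0.3 and 0.595 with an estimated correlation), and the mitosis call there also ended without vehicle replicate 2 of either time point. For SV40T cells camera gave adjusted p = 2.08e-06 for DNA replication, 2.94e-06 for mitosis, 1.71e-06 for interferon, 6.01e-12 for macrophage and 0.000823 for epithelial genes (adjusted p = 0.232, 0.232, 0.219, 0.158 and 0.158 with an estimated correlation). Across genes, changes over time in control and vehicle cells correlated at r = 0.706 (Spearman rho 0.581), and those in control and SV40T cells at r = 0.257 (rho 0.223), genes not being independent replicates. Of 2644 genes called in control and vehicle cells, 70 moved in opposite directions, and of 2933 called in control and SV40T cells, 963 did.

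The difference between time points was tested as an interaction. The difference between SV40T and vehicle cells changed in 4815 genes (3292 more positive, 1523 more negative at time point 2), among them Msln by 5.43, Upk3b by 5.26 and Lyz2 by -5.64 on the log2 scale. Of the genes called, 68.37% were more positive, against 50.9% after median-ratio scaling and 52% after quantile normalization, and the median of all genes was 0.139. The difference between vehicle and control cells changed in 967 genes (522 and 445), with Mki67 at 0.90. That count was 31 when only those groups were fitted, 1675 when vehicle replicate 1 of time point 1 was also left out, 146 after the GC trend was removed, and between 278 without control replicate 2 of time point 1 and 2212 without vehicle replicate 3 of time point 1. It was 314 without control replicate 3 and 1572 and 2159 without vehicle replicates 2 and 1 of time point 1, and 347, 511, 313, 577 and 427 without control replicates 1 and 3 and vehicle replicates 1, 2 and 3 of time point 2.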

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

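The test of epithelial genes against dilution, the test of mesothelial genes at time point 1, the medians that include genes below the filter, and the corrections for length and GC trends were chosen after results had been seen. The results below stood out because the effect of a treatment differed between the time points in a test of that difference.

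Between SV40T and vehicle cells 4815 genes differed in this way, Msln by 5.43, Upk3b by 5.26, Krt14 by 5.17, Upk1b by 4.57, C1qc by -4.10, C1qb by -4.24, C1qa by -4.54 and Lyz2 by -5.64 on the log2 scale. Trp53 differed by 0.26, a call that ended after either scaling and in a fit of only these groups. It also ended without SV40T replicate 1 or 2 of time point 1, SV40T replicate 1 or 3 of time point 2, vehicle replicate 2 of time point 1 or vehicle replicate 2 or 3 of time point 2. Cdkn1a differed by -0.32, a call that ended with array weights and in a fit of only these groups. It also ended without SV40T replicate 1 or 2 of time point 1, SV40T replicate 2 of time point 2, vehicle replicate 2 of time point 1 or vehicle replicate 1 or 2 of time point 2. The lists whose change was more positive at time point 2, given as medians of the difference on the log2 scale, were DNA replication (0.98), mitosis (0.74), chromatin (0.80), homologous recombination (0.57), interferon (0.94), cholesterol synthesis (1.54) and epithelial genes (3.92). Those whose change was more negative were collagens (-0.59), matrix proteases (-0.29), contractile genes (-0.65), senescence factors (-0.46), glycolysis (-0.47), macrophage genes (-2.82) and adipocyte genes (-0.83). None of these list calls held with an estimated correlation, the smallest being adjusted p = 0.0614, and the adipocyte call ended after quantile normalization. Of 119 other named genes, 92 were called for this difference.

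Between vehicle and control cells 967 genes differed between the time points. The largest were mt-Atp8 (1.53), mt-Nd5 (1.46), Hmmr (1.31), Serpina3n (1.25), Rps29 (-1.64), Romo1 (-1.65), Atp5k (-2.12) and CAAA01147332.1 (-2.22), and Mki67 was at 0.90. These calls ended in a fit of only these groups, except that of CAAA01147332.1. The calls of mt-Nd5 and Serpina3n also ended after the GC trend was removed, that of mt-Nd5 without any control library or any vehicle library of time point 2, and that of Serpina3n without control replicate 1 or 2 of time point 1, control replicate 2 or 3 or vehicle replicate 2 or 3 of time point 2. List medians were 0.18 for DNA replication, 0.58 for mitosis, 0.46 for chromatin, 0.35 for homologous recombination, 0.21 for interferon, -0.23 for glycolysis, 0.90 for mitochondrially encoded and 0.60 for neural and glial genes. The mitochondrially encoded list alone held with an estimated correlation (adjusted p = 0.00982). The interferon call ended without control replicate 1 or 3 or vehicle replicate 2 or 3 of time point 1, or control replicate 2 or vehicle replicate 3 of time point 2. The glycolysis call ended without control replicate 2 of time point 2, and that of DNA replication without vehicle replicate 2 or 3 of time point 1, or control replicate 3 or vehicle replicate 1 of time point 2. Of 65 other named genes, 33 were called.

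Macrophage genes were low in SV40T cells at time point 2. A second list of macrophage genes also fell, 17 of 17 tested, with a median change of -3.16 on the log2(FPKM + 0.1) scale (from -5.30 to -1.47), where a median above -0.5 would have argued against a smaller share of macrophages. Its most abundant members in vehicle cells, Cd53, Mpeg1 and Lcp1, averaged 6.95, 5.11 and 4.71 FPKM there and 0.254, 0.477 and 0.426 in SV40T cells, and 16 and 14 of the 17 genes rose over time in control and vehicle cells. The 5 tested epithelial genes, all keratins, had a median change of 4.79 (from 2.51 to 8.59), or 0.80 with the 7 below the filter on low values included, and did not decide whether overgrowing cells diluted every other type alike, since those cells could themselves carry epithelial genes. The values are consistent with a smaller share of macrophages in the SV40T cultures, by loss or by dilution, but a fall of these genes within cells was not tested and stays open.

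Mesothelial and keratin genes were high in SV40T cells at time point 2. A list of mesothelial genes, not looked at before, had a median change of 3.72 over the 10 that passed the filter on low values and 3.15 over all 12, with 9 above 1, Dsp at 0.63, Calb2 at 0.00 and Nkain4 at -2.41, where a median under 0.5 would have argued against a larger share of mesothelial cells. Wt1, a transcription factor of mesothelium, averaged 14.1 FPKM against 0.563 in vehicle cells, and Gpm6a 15.1 against 0.0187. Their median at time point 1 was 0.16 (from -0.84 to 1.79), which argues against an immediate induction of the set by large T antigen in all cells, since its transcript was already at 195 FPKM, but Ildr2 (1.79) and Gpm6a (1.13) were already called higher then, and Bnc1 (-0.84) lower. Outgrowth of mesothelial-like cells may account for the pattern, and a slower change within fibroblasts stays open.

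Vehicle and control cells differed in 4132 genes at time point 1 but in 8 at time point 2. Without vehicle replicate 1, 4165 genes were called and 76.8% of the original calls were kept, which argues against its length trend as the whole cause. Leaving out that library also raised counts where it was not compared, from 4501 to 6759 over time in control cells. After the length and GC trends were both removed 2474 genes were called, above the bound set for that count. The count cannot decide on these trends, since it includes genes not called before, and 37.7% of the original calls were kept. Removing the GC trend alone left 1812, under the bound set for both trends together, so the GC trend could account for a large part. A response to infection, which the design names, was not tested apart from these trends and stays open.

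The 3 libraries against 3 of each pairwise comparison give 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real and highest other counts were 5925 and 0 for SV40T against vehicle at time point 1, 8218 and 0 at time point 2, 4132 and 3 for vehicle against control at time point 1, 8 and 3 at time point 2, and 5345 and 0 and 7961 and 0 for SV40T against control. Over time they were 4501 and 0 in control, 5219 and 1 in vehicle and 7081 and 0 in SV40T cells. For the differences between time points 6 of 100 splits gave as many as 4815 genes (highest other 8521) and 6 of 100 as many as 967 (highest other 1907), so chance was not excluded by this count. Of the 5 others in each case, 1 (8521 and 1791 genes) kept the real groups at both time points with the labels exchanged at one, so it adds the real differences and is no chance split. The other 4 kept the real groups at time point 2 and time point 1, respectively, which is itself a structure of the samples, and the 77 and 81 splits that broke the groups at both gave at most 1 and 3 genes.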

How the results depend on the processing

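The alternatives that removed length or GC trends, left out vector rows, or left out vehicle replicate 1 of time point 1 where it was not compared or in a fit of only the groups compared, were chosen after seeing the data. Of the counts under alternatives 202 stayed within 1.5 times, 12 were larger and 29 smaller. For named genes 10543 values kept their side of the threshold, and their direction where called, and 553 lost a call, 207 of them by the 2-fold rule. A further 45 gained a call, and 4 turned direction with a call before or after, turns without a call not being counted. For lists the numbers kept, lost, gained and turned were 5007, 195, 106 and 6, and 111 of the 195 losses came with the estimated correlation. Depth is unknown and sets no limit that can be given. Except where stated, the cause was not tested.

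Requiring a 2-fold change lowered all counts by construction, to 637 and 2102 for SV40T against vehicle at time points 1 and 2, 99 and 5 for vehicle against control, 569 and 1999 for SV40T against control, 470, 572 and 988 over time in control, vehicle and SV40T cells, and 1128 and 98 for the differences between time points of SV40T and of vehicle. Array weights gave 8354 for SV40T against control at time point 1, 7327 over time in control cells, 28 for vehicle against control at time point 2 and 1665 for its difference between time points. Fitting only the groups compared gave 2867 for SV40T against vehicle at time point 1, 1939 over time in vehicle cells, 30 for vehicle against control at time point 1 and 31 for its difference between time points, and the last was 1675 when vehicle replicate 1 was also left out, so the spread of that library lowered it. Removing the GC trend gave 1812 and 146 for those vehicle comparisons, and removing both trends 2474 and 459. For vehicle against control at time point 2 the table without a filter gave 25 and the table without vector rows 3, by construction.

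Leaving out single libraries gave 4679 to 6545 and 7536 to 9757 genes for SV40T against vehicle, 2490 to 5408 and 7 to 24 for vehicle against control, and 4406 to 7548 and 7281 to 9508 for SV40T against control. Over time it gave 3601 to 6759 in control, 3994 to 6075 in vehicle and 6165 to 8875 in SV40T cells, and for the differences between time points 4037 to 6569 and 278 to 2212.

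The contractile median of SV40T against vehicle at time point 1 was 0.01 after quantile normalization against -0.33. With FPKM of at least 5 the neural and glial medians of SV40T against control were 0.32 and 0.65 against -0.48 and -0.85, few members being left. For vehicle against control at time point 2, leaving out libraries moved the contractile median from -0.08 to 0.19, mitosis from -0.07 to 0.05 and senescence factors from -0.01 to 0.08. With both trends removed Adamts5 was 0.02, Lamp2 0.11 and Twist1 -0.00 for vehicle against control at time point 1, against -0.35, -0.31 and 0.49, and Atr was -0.08 over time in vehicle cells against 0.49.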

Other observations

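Fos, an immediate early transcription factor, fell from 43.8 ± 1.23 to 2.3 ± 0.485 FPKM in control (13.9-fold, adjusted p = 5.11e-12) and from 55.9 ± 8.64 to 2.38 ± 0.283 in vehicle cells (17.4-fold). Nr4a1, a nuclear receptor of the same response, fell from 79.4 ± 1.51 to 14.8 ± 0.981 in control cells (5.16-fold) and from 102 ± 17.9 to 16 ± 2.98 in vehicle cells (6.31-fold). Chchd10, a mitochondrial protein, fell from 43.3 ± 2.51 to 4.72 ± 1.11 in control cells (7.94-fold). In SV40T cells Trib3, a pseudokinase induced by amino acid shortage, fell from 69.1 ± 3.92 to 7.22 ± 0.552 (9.88-fold), and Ppp1r15a, which restores translation after stress, from 70.6 ± 5.73 to 7.62 ± 0.762 (9.63-fold). The list of the unfolded protein and integrated stress response fell in 11 and rose in 6 of 20 in SV40T cells (11 and 6 adjusted over the list alone, median -1.01 relative to all genes, camera adjusted p = 4.05e-05, and adjusted p = 0.158 with an estimated correlation). It also fell over time in vehicle cells, in 11 and rising in 3 of 20 (11 and 3, median -0.58, adjusted p = 6.12e-05, and adjusted p = 0.165 with an estimated correlation), and in control cells, in 10 and rising in 1 (11 and 2, median -0.32, adjusted p = 0.000468, and adjusted p = 0.143 with an estimated correlation). The difference of this change between SV40T and vehicle cells did not pass (adjusted p = 0.0917). The summed FPKM of the list, to which abundant members contribute most, rose in SV40T cells from 2069 ± 65.8 to 2258 ± 28.1. It fell in vehicle cells from 2083 ± 314 to 1839 ± 23.8 and in control cells from 2049 ± 73.1 to 1830 ± 70.2. Between SV40T and vehicle cells the list did not pass at time point 1 (8 higher and 4 lower of 20, adjusted p = 0.542) or time point 2 (8 and 7, adjusted p = 0.333). At time point 2 its median and mean were positive before the median of all genes, 0.243, was subtracted, and the test direction was down.

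Glycolysis genes fell over time in SV40T cells in 11 and rose in 1 of 17 (11 and 1, median -0.70, adjusted p = 5.75e-06, and adjusted p = 0.219 with an estimated correlation), with Slc2a1, the glucose transporter Glut1, falling from 43.6 ± 3.37 to 21.3 ± 0.81 FPKM (2.31-fold). Against vehicle cells glycolysis did not pass at time point 1 (adjusted p = 0.481) and fell in 8 and rose in 1 of 17 at time point 2 (8 and 1, median -0.54, adjusted p = 0.00116, and adjusted p = 0.289 with an estimated correlation). Cholesterol synthesis genes, lower in SV40T than vehicle cells at time point 1, were higher at time point 2 in 17 and lower in 1 of 20 (17 and 1, median 0.40, adjusted p = 0.0191, and adjusted p = 0.43 with an estimated correlation). They fell over time in vehicle cells in 19 of 20 (20, median -1.01, adjusted p = 3.95e-14, and adjusted p = 0.139 with an estimated correlation), where Insig1, a brake on sterol synthesis that is itself induced by low sterol, fell from 56.2 ± 2.49 to 18.7 ± 0.494 (3.01-fold). Lysosome genes fell over time in control cells in 16 of 24 (16, median -0.52, adjusted p = 1.09e-08, and adjusted p = 0.0835 with an estimated correlation). They fell in 15 and rose in 1 in vehicle cells (16 and 1, median -0.39, adjusted p = 4.25e-08, and adjusted p = 0.165 with an estimated correlation), and fell in 12 and rose in 1 in SV40T cells (12 and 1, median -0.44, adjusted p = 5.64e-06, and adjusted p = 0.158 with an estimated correlation). Between SV40T and vehicle cells lysosome genes fell in 11 and rose in 1 of 24 at time point 1 (11 and 1, adjusted p = 0.000349, and adjusted p = 0.191 with an estimated correlation) but did not pass at time point 2 (adjusted p = 0.0798). Mitochondrially encoded genes were lower in SV40T than vehicle cells in 7 of 13 (8) at time point 1 and 6 of 13 (4) at time point 2 (adjusted p = 0.000486 and 0.00592, and adjusted p = 0.0522 and 0.0906 with an estimated correlation), calls that ended after quantile normalization.

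In SV40T against vehicle cells, CDK inhibitors rose in 4 of 7 at time point 1 (4, adjusted p = 0.414) and rose in 5 and fell in 1 of 7 at time point 2 (5 and 1, adjusted p = 0.373), with Cdkn2c, the inhibitor p18Ink4c, at 33.6 ± 0.583 against 8.32 ± 0.903 FPKM at time point 2 (3.14-fold). Of 26 p53 targets 12 rose and 4 fell at time point 2 (11 and 4, adjusted p = 0.725). Their median was 0.25, close to the median of all tested genes, 0.243, and the test direction was down. Macrophage genes at time point 1 rose in 8 of 15 (9, adjusted p = 0.0917), and that list passed without vehicle replicate 1. The 5 tested epithelial genes at time point 1 had 1 higher and 1 lower (adjusted p = 0.723, median -0.01 and mean 0.15). Fibroblast identity genes at time point 2 fell in 5 and rose in 3 of 12 (5 and 3, adjusted p = 0.0248, and adjusted p = 0.0702 with an estimated correlation), a call that ended after quantile normalization. The lists of endothelium (3 tested genes, adjusted p = 0.996 and 0.725 at time points 1 and 2), skeletal muscle (4 genes, adjusted p = 0.0917 and 0.657), neural and glial cells (7 genes, adjusted p = 0.481 and 0.0875) and, at time point 1, adipocytes (5 genes, adjusted p = 0.151) did not pass. The endothelial median at time point 1 was -0.39 and its mean 0.25, and the muscle median at time point 2 was 0.25 and its mean -0.35. These values are not relative to the median of all genes, which was 0.110 at time point 1 and 0.243 at time point 2.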
